A study of Mus musculus and Homo sapiens with 12 samples.

How the data were processed

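RNA was sequenced from 12 samples, 3 biological replicates each of KPC, KPC LM2, PANC1 and PANC1 LM3, prepared as total RNA with a TruSeq RNA kit per the labels' protocols. The protocols give liver tumours as the source of the RNA, and the sample titles name cells. Per the submitters' processing notes, the tools named were STAR 2.7.6a, featureCounts 2.0.0, MultiQC 1.9 and DESeq2 1.24, and the genome builds mm39 and hg19; the notes used here give neither their settings nor the annotation or the model design.

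Each model was analysed from 1 table of the authors' own comparison of the 2 groups, and the columns used hold no value per library. The mean normalised count is headed baseMean, and the headers do not define it. It is read here, as in DESeq2, as a signal the authors computed over libraries as counts divided by size factors. Log2 fold changes and their standard errors were deposited on the log2 scale, without shrinkage as far as the values show. A score, the Wald statistic, was deposited for each gene and equalled the log2 fold change over its standard error within 9.2e-08. Deposited p-values equalled the two-sided normal p of that statistic within 5.0e-08, and the adjusted p-values equalled a Benjamini-Hochberg adjustment over the genes that have one within 2.5e-06. An adjusted p was listed for 20,050 of 23,201 KPC genes, at a mean normalised count of 3.08 or more, and for 17,838 of 18,190 PANC1 genes, at 1.08 or more. A signed negative log10 of the p-value was also deposited and was not used for any result. In PANC1, 25 genes have a p listed as 0. The column names do not say which group is the numerator of the fold change, and neither the labels nor the values were used to assign it.

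The planned count test could not be run on these columns, so genes called are those with an adjusted p under 0.05 in the authors' deposited tables. Named genes followed a rule fixed before the data were examined: the 8 most positive and 8 most negative log2 fold changes among called genes, leaving out clone and identifier names and host marker genes; up to 4 members per list and direction with the smallest adjusted p, with other members as contrasts; the 8 genes per sign called in both models with the largest smaller fold change; and the drivers of this cancer, of which CDKN2A and SMAD4 are named. Some genes that the rule selects are not reported here. Host markers named for their abundance were chosen after their values were seen. The conditions of that rule on level and overlap of replicates need values per sample and were not applied.

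Gene lists fixed before the data were examined (34 lists, of which 32 in KPC and 31 in PANC1 had 5 or more tested genes) covered host cell markers, tumour programmes, tissue handling and ribosomal and mitochondrially encoded genes. The mitochondrially encoded list had 0 genes tested. Lists were tested with the pre-ranked form of camera in limma 3.58.1 (R 4.3.3) on the Wald statistic of genes with an adjusted p, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. A correlation estimated from the samples could not be had, and the rotation test was not run, since both need values per library. Each list's median log2 fold change was set against 10000 random lists matched on mean normalised count in 20 ranges. Models were compared over gene symbols matched in capitals, with Fisher's exact test per pair of signs; the difference between models per list was tested with camera on the difference of fold changes over its combined standard error. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

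Alternatives were a stricter adjusted p of 0.01, an absolute log2 fold change over 1, adjustment over all genes with a p, host markers left out, genes with a mean normalised count of 64 or more, recentring on those genes, a t distribution with 4 degrees of freedom, subtraction of a running median of the fold change over 501 genes ordered by level, a preset correlation of 0.05, ranks, and log2 fold changes in place of the statistic. Mouse gene order, exonic length and GC content were taken from RefSeq and GENCODE annotation of GRCm38, another build than the authors' mm39, so no coordinates are given; 8749 of the 8752 genes at a mean normalised count of 100 or more were placed. Human gene positions were not used here.

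The steps were tested on simulated data. Normal errors were drawn from the listed standard errors, and only genes with a mean normalised count of 64 or more were changed. Of these, 66% of 100 KPC genes changed by 1 on the log2 scale and 98% of 100 changed by 2 were called among 20,050 genes. In PANC1 the shares were 99% and 100% among 17,838 genes. The shares do not hold for genes under 64, where the median listed standard error was 0.998 in KPC and 0.69 in PANC1. For the list test, statistics were shuffled over genes and 5 lists were moved by a set amount. The test called 98% of moved lists in KPC and 96% in PANC1, and 0.72% and 0.42% of unmoved lists. Shuffling removes correlation between genes, so these shares do not cover lists of correlated genes. The replicates are labelled biological; which animals they came from is not given in the sources used here, so p-values measure the spread between these samples. Depth per sample is unknown, and precision is given by the listed standard errors, with a median of 0.24 for KPC and 0.09 for PANC1 genes at 64 or more.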

Results

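Gene expression was profiled by RNA sequencing of pancreatic ductal carcinoma grown in the liver in 2 models, with 12 samples in 4 groups of 3 biological replicates. KPC is a mouse pancreatic ductal carcinoma line, and KPC LM2 is its derivative after 2 generations of selection in vivo for liver metastasis. PANC1 is an established human pancreatic ductal carcinoma line, and PANC1 LM3 is its derivative after 3 generations of the same kind of selection. Per the labels' protocols, 500,000 cells were given by intrasplenic injection on day 1, liver tumours were collected on day 21, and RNA was taken from these tumours. The sample titles name cells and not tumours, so whether whole tumour tissue or cells recovered from it were sequenced is not settled by the labels. The question for each model was how samples of the selected line differed from samples of the line it came from. Values came as 1 comparison table per model, with 1 row per gene and no value per library, so the sequencing depth of each sample is unknown. Mean normalised counts summed to 9106250 over the 23,201 genes of the authors' deposited table for KPC, and to 15415400 over the 18,190 genes of the authors' deposited table for PANC1. The tables do not name the group in the numerator of the fold change. Values are therefore given as positive or negative, as listed, and neither sign is assigned to the parental or to the selected line. Errors after ± are the standard errors (SE) listed by the authors on the log2 scale.

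Between KPC and KPC LM2 samples, the collagen VI chain genes had the largest positive fold changes among ranked genes with a mean normalised count of 64 or more. Ranked genes were those called, without clone and identifier names and host marker genes. An imprinted zinc finger gene had the smallest adjusted p of all genes, with a negative fold change. In the authors' deposited table for KPC, Col6a1 and Col6a2, which encode chains of collagen VI, were listed at 5.24 ± 0.27 and 5.44 ± 0.37 on the log2 scale. The adhesion G protein-coupled receptor gene Adgrg7 followed at 4.90 ± 0.76 and Avil, the actin-binding protein advillin, at 4.42 ± 0.36 in the authors' deposited table. Aim2, a sensor of cytosolic DNA, was at 4.21 ± 0.41 and the GABA-A receptor subunit gene Gabrp at 3.98 ± 0.50 in the authors' deposited table. Hoxb6, a homeobox gene, and Ifitm1, an interferon-induced membrane protein gene, completed the 8 largest positive values of ranked genes. They were at 5.63 ± 1.12 and 4.09 ± 1.15 in the authors' deposited table, with mean normalised counts of only 21.8 and 11.2. On the negative side, the authors' deposited table listed Peg3, a paternally expressed imprinted gene, at -5.25 ± 0.20 with a mean normalised count of 2295 and the Wald test's adjusted p of 7.65e-153. Dgkk, a diacylglycerol kinase gene, was at -4.94 ± 0.44 in the authors' deposited table. The other 6 of the 8 most negative ranked genes were close to the detection floor, with mean normalised counts from 5.25 for Irx2 to 17.1 for Tmem47 in the authors' deposited table. They were Eif2s3y (-5.79 ± 1.17) and Uty (-5.26 ± 1.51), both on the Y chromosome, Lmo1 (-5.62 ± 1.46), Tmem47 (-5.46 ± 0.98), Irx2 (-5.24 ± 1.48) and Ap1m2 (-4.95 ± 1.23), all as given in the authors' deposited table. Since the tables do not show whether a group was at 0, the fold of such a gene is a fitted value and no bound. After a running median over expression level was subtracted, the calls of Lmo1, Uty, Irx2 and Ap1m2 were lost, with adjusted p-values of 0.061, 0.16, 0.14 and 0.058. Their log2 fold changes went from -5.62, -5.26, -5.24 and -4.95 to -4.22, -3.63, -3.66 and -3.60, with the SE as listed. Of the pancreatic cancer drivers reported here, the authors' deposited table listed Cdkn2a at 0.37 ± 0.30 and Smad4 at 0.20 ± 0.18, neither of them past the Wald test's threshold. Smad4 was at -0.02 after recentring on genes at 64 or more and at -0.04 after the level trend was subtracted, so its sign is not settled.

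**Figure D1:**
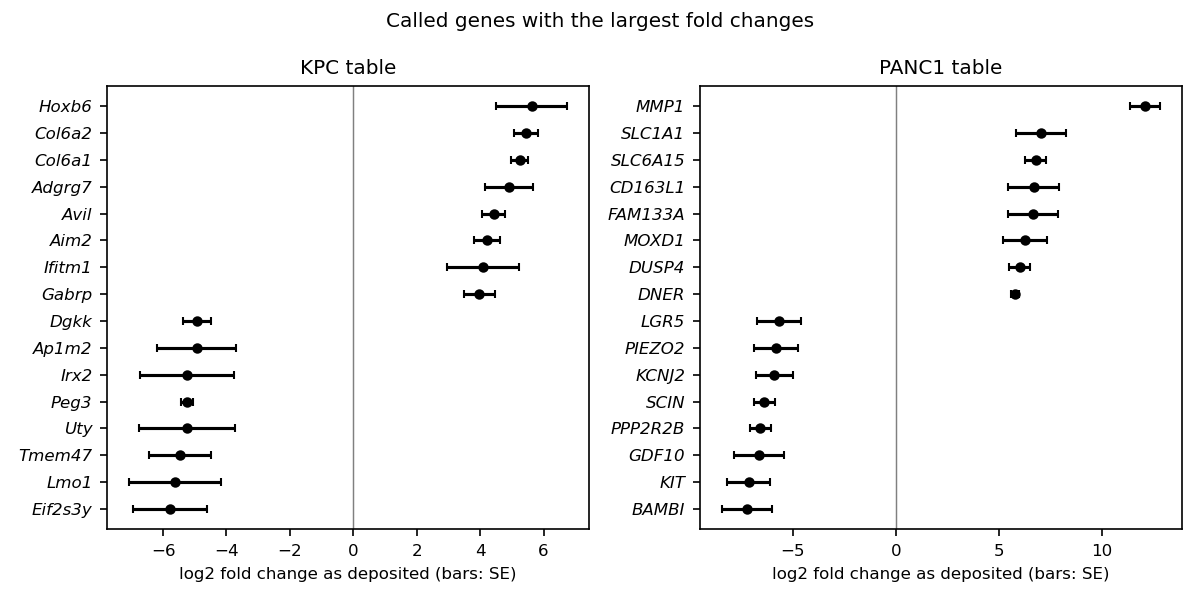
Called genes with the largest fold changes in each model, chosen by the rule fixed before the data were examined. The x axis is the log2 fold change as listed in the authors' deposited table, points are genes and bars are the authors' SE; KPC values run from -5.79 (Eif2s3y) to 5.63 (Hoxb6) and PANC1 values from -7.23 (BAMBI) to 12.09 (MMP1).

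Over all genes, the authors' deposited table for KPC gave 2079 of 20,050 tested genes with a Wald test adjusted p under 0.05, of which 1157 were positive and 922 negative. An absolute log2 fold change over 1 was listed for 1303 of the called genes in the authors' deposited table, 481 of them positive and 822 negative. The 2 signs lay at different expression levels. Among the 10,407 genes with a mean normalised count under 16, the median log2 fold change in the authors' deposited table was -1.45 (quartiles -2.11 and -0.70), 89.7% were negative, and 412 of the 421 called were negative. Among the 9769 genes at 64 or more, the median in the authors' deposited table was 0.22 (quartiles -0.02 and 0.45), and 1031 of the 1237 called were positive. With fold changes recentred on those 9769 genes, a shift of 0.22, 2149 genes passed, and the share of positive calls went from 55.7% to 23.5%. Only the normal approximation of the Wald test was listed by the authors. Read against a t distribution with 4 degrees of freedom, 0 KPC genes passed the adjusted threshold and 2132 had an unadjusted p under 0.05. Even Col6a1, with a Wald statistic of 19.5, had an adjusted p of 0.41 by that t distribution. The count of 0 therefore does not separate weak from strong calls.

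**Figure D2:**
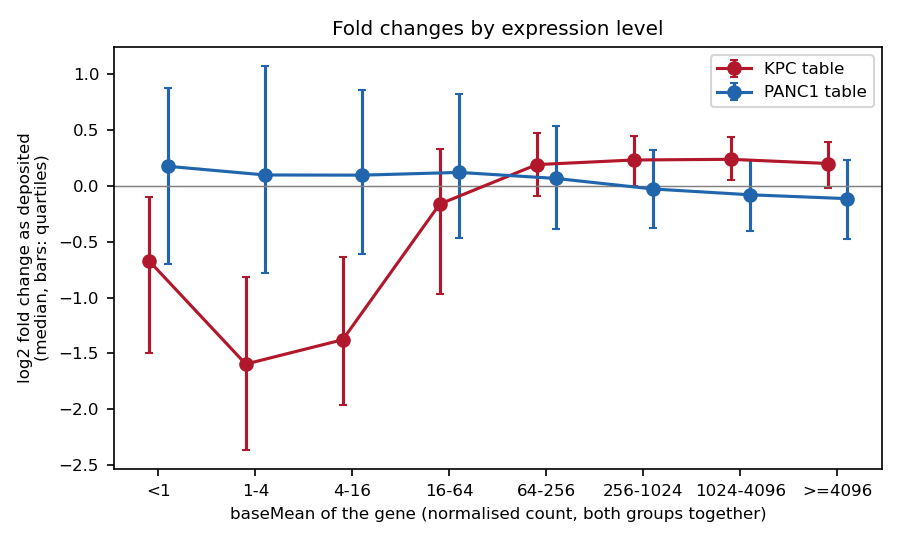
Log2 fold changes by expression level. The x axis is the mean normalised count of a gene over both groups, the y axis the log2 fold change in the authors' deposited table; points are medians of all listed genes in the range and bars their quartiles. The KPC medians go from -1.60 at 1 to 4 and -1.38 at 4 to 16 to 0.23 at 256 to 1024, and the PANC1 medians stay between -0.11 and 0.18.

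Interferon-stimulated and class I antigen presentation genes of the KPC model stood on the positive side. Of 27 interferon-stimulated genes tested, 8 were positive and 2 negative past the threshold over all genes, and the same counts held when adjusted over the list alone. Examples in the authors' deposited table were Oasl1 at 2.16 ± 0.38, Herc6 at 1.23 ± 0.29, Lgals3bp at 1.22 ± 0.23 and, on the other side, Cmpk2 at -3.35 ± 1.19 with a mean normalised count of 4.83. The list stood above other genes in the camera test (adjusted p = 0.012), and its median log2 fold change of 0.39 lay at percentile 99.97 of random lists of like expression, which take genes as independent. Of 13 class I presentation genes, 3 were positive and none negative over all genes and adjusted over the list alone (camera adjusted p = 0.012, median 0.32 at percentile 94.87 of random lists). These were the class I heavy chain gene H2-K1 (1.92 ± 0.22), the light chain gene B2m (1.04 ± 0.30) and the chaperone gene Calr (0.86 ± 0.23) in the authors' deposited table. Of 7 class II presentation genes tested none was called in either count, 5 were listed with negative values, and the median was -0.97, at percentile 78.12 of random lists of like expression (camera adjusted p = 0.55). After the level trend was subtracted the class II test pointed to the positive side (adjusted p = 0.53), and its difference from class I was not tested. With genes at 64 or more alone the class I list had a camera adjusted p of 0.052, and on ranks the interferon and class I lists were at 0.059 and 0.054. With a preset correlation of 0.05 in place of 0.01, the 4 of 11 KPC list calls left were the cell cycle, glycolysis, immediate-early and matrix lists, and the interferon list was at 0.079.

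Immediate-early and heat-shock genes, a list that can reflect tissue handling, were also on the positive side in KPC. Of its 22 members 8 were positive and 0 negative over all genes, and 10 and 0 when adjusted over the list alone (camera adjusted p = 1.7e-05). The authors' deposited table listed Fos at 1.60 ± 0.21, Egr1 at 1.73 ± 0.27, Atf3 at 1.86 ± 0.30 and Nr4a1 at 1.40 ± 0.29. Basement membrane and matrix genes had 7 positive and 1 negative of 25 over all genes, and 8 and 2 when adjusted over the list alone (camera adjusted p = 3.2e-07). Besides the collagen VI genes, the laminin chain gene Lamb3 (1.55 ± 0.22) was positive in the authors' deposited table, and Col12a1 was at -1.73 ± 0.51. The matrix list had a median of 0.05 at percentile 8.42 of random lists and a mean of 0.41, so its call does not show a shift of the typical member. Its camera adjusted p was 0.11 on ranks, 1.3e-06 at 64 or more and 5.1e-05 after the level trend was subtracted, positive in each. Matrix protease and inhibitor genes were mainly negative, 7 against 1 of 24 over all genes and 7 against 2 adjusted over the list alone (camera adjusted p = 0.013, 0.16 on ranks and 0.00014 after the level trend was subtracted). In the authors' deposited table the urokinase gene Plau was at -1.65 ± 0.19, Adam12 at -1.54 ± 0.22 and the protease inhibitor gene Timp3 at -1.03 ± 0.18, while the urokinase receptor gene Plaur was at 0.58 ± 0.18.

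Cell cycle, glycolysis, oxidative phosphorylation and TGF-beta target genes of KPC were called positive as lists, but these lists hold well-expressed genes and their calls went with expression level. Of 30 cell cycle genes 5 were positive and 0 negative, with Cenpf at 0.88 ± 0.19 and Ccnb2 at 0.79 ± 0.21 in the authors' deposited table (camera adjusted p = 0.00039). Of 19 glycolysis genes 5 were positive and 0 negative, with Pfkp at 1.52 ± 0.22 and Hk1 at 0.81 ± 0.18 in the authors' deposited table (camera adjusted p = 0.001). Counts adjusted over the list alone were the same for both. TGF-beta targets had 5 positive and 1 negative of 20 over all genes and 6 and 1 adjusted over the list alone, among them Tgfb1 at 1.03 ± 0.22 and Ltbp2 at -1.71 ± 0.40 in the authors' deposited table (camera adjusted p = 0.013). Oxidative phosphorylation had 1 positive call of 27, Sdhb, at 0.72 ± 0.20 in the authors' deposited table (camera adjusted p = 0.0061). Against random lists of like expression, the median of the cell cycle list lay at percentile 94.61 and that of glycolysis at 88.1. Oxidative phosphorylation lay at 62.3 and TGF-beta targets at 93.16. After a running median over expression level was subtracted, the camera adjusted p-values were 0.58 for cell cycle, 0.15 for glycolysis, 0.74 for oxidative phosphorylation and 0.58 for TGF-beta targets. In that setting 2 lists not called before were called negative, beside the protease list. Cholesterol synthesis and uptake went from an adjusted p of 0.40 to 0.00069 and YAP/TAZ targets from 0.25 to 6.0e-05. With log2 fold changes in place of the statistic and no trend subtracted, both tests pointed to the positive side (camera adjusted p = 0.29 and 0.39). The authors' deposited table listed the sterol pathway genes Fdps at -0.72 ± 0.19 and Dhcr7 at -0.83 ± 0.29, and the YAP/TAZ target Ccn2 at -0.88 ± 0.17. Cholesterol genes had 0 positive and 3 negative of 25 over all genes, and 0 and 4 adjusted over the list alone. YAP/TAZ targets had 1 and 2 of 17 in both counts. The median of the cholesterol list lay at percentile 0.19 of random lists of like expression, and that of the YAP/TAZ list below all 10000.

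Epithelial and mesenchymal genes of KPC went both ways, and neither list was called. Of 26 epithelial genes 4 were positive and 7 negative, with the keratin gene Krt7 at 1.18 ± 0.18 against the claudin gene Cldn4 at -1.99 ± 0.28 and the membrane protease gene St14 at -2.05 ± 0.33 in the authors' deposited table. Of 22 mesenchymal genes 5 were positive and 2 negative, with Twist1 at 2.23 ± 0.39 and S100a4 at 1.62 ± 0.25 against the N-cadherin gene Cdh2 at -1.47 ± 0.34 in the authors' deposited table. Adjusted over the list alone the counts were 6 and 7, and 5 and 3. RAS-MAPK output genes had 3 positive and 1 negative of 23 over all genes, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.25), and ribosomal protein genes had none called of 29 in either count, though 3 of all 82 cytosolic ribosomal protein genes were called. The mesenchymal list had a median of -0.20 with a positive mean and a positive camera direction (adjusted p = 0.54), and that median lay below all 10000 random lists of like expression. The epithelial median lay at percentile 4.94.

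Markers of host cells that a liver tumour sample could hold were mostly near the detection floor in KPC. In the authors' deposited table the median mean normalised count of the tested members was 10.4 for hepatocytes, 10.8 for leukocytes, 14.1 for fibroblasts and 13.2 for endothelium. Leukocyte and fibroblast markers were called negative as lists (camera adjusted p = 0.016 and 0.013), and 0.67 and 0.53 after the level trend was subtracted. The authors' deposited table listed the macrophage gene Adgre1 at -2.88 ± 0.75 and the collagen gene Col1a1 at -1.84 ± 0.63. Of the 87 host markers tested, 7 had a mean normalised count of 64 or more. The most abundant was the apolipoprotein gene Apob of the hepatocyte list, at -0.13 ± 0.32 with a mean normalised count of 9009 in the authors' deposited table, where the albumin gene Alb had 10.4. The VEGF receptor gene Flt1 was at 2.53 ± 0.22 with a mean normalised count of 1252, and Flt4 of the same family at -1.69 ± 0.24 with 256, in the authors' deposited table. Over all genes, 0 positive and 2 negative calls were made among 18 leukocyte markers, and 1 and 1 among 18 fibroblast and among 18 endothelial markers. Adjusted over the list alone these were 0 and 2, 1 and 2, and 1 and 2, and the endothelial list was not called (camera adjusted p = 0.25). The 3 remaining marker lists had 1 negative call of 19 tested hepatocyte genes, 1 negative of 4 erythroid genes and 1 positive of 10 acinar and islet genes, over all genes and adjusted over the list alone.

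Between PANC1 and PANC1 LM3 samples the collagenase gene MMP1 had the largest fold change among genes ranked by the same rule. It was at 12.09 ± 0.72 with a mean normalised count of 2579 in the authors' deposited table. Also positive in the authors' deposited table were the Notch ligand gene DNER (5.77 ± 0.20), the ERK phosphatase gene DUSP4 (64.1-fold, with an SE of 0.51 on the log2 scale) and the amino acid transporter genes SLC6A15 (6.79 ± 0.50) and SLC1A1 (7.03 ± 1.22). The rest of the 8 largest positive values of ranked genes in the authors' deposited table belonged to CD163L1 (6.70 ± 1.23), FAM133A (6.65 ± 1.23) and MOXD1 (6.27 ± 1.07), each with a mean normalised count under 64. SLC1A1 was also under 64, at 21.2. The most negative ranked gene in the authors' deposited table was BAMBI, a decoy receptor of the TGF-beta family, at -7.23 ± 1.21, followed by the receptor tyrosine kinase gene KIT at -7.11 ± 1.04. PPP2R2B, a phosphatase subunit gene, was at -6.56 ± 0.50 and the actin-severing protein gene SCIN at -6.37 ± 0.53 in the authors' deposited table. GDF10 (-6.63 ± 1.22), KCNJ2 (-5.88 ± 0.88), PIEZO2 (-5.82 ± 1.07) and the WNT-associated stem cell gene LGR5 (-5.67 ± 1.08) completed the 8, all in the authors' deposited table. PPP2R2B and SCIN had mean normalised counts of 158 and 122, and the others were under 64, from 19.0 (LGR5) to 51.0 (KIT). As in KPC, whether a group was at 0 is not shown, so the fold of such a gene is a fitted value. Of the drivers reported here, the authors' deposited table listed SMAD4 at -0.14 ± 0.07 with the Wald test's adjusted p of 0.117. CDKN2A had no row in the authors' deposited table for PANC1.

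In all, 9361 of the 17,838 PANC1 genes tested were called in the authors' deposited table, 4634 positive and 4727 negative. A log2 fold change beyond 1 in either direction was listed for 2759 of them in the authors' deposited table, 1450 positive and 1309 negative. Median SE in the authors' deposited table was 0.09 for PANC1 genes at a mean normalised count of 64 or more and 0.24 for KPC genes at that level, so smaller changes could be called in PANC1.

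All 30 cell cycle genes tested in PANC1 were negative past the threshold, over all genes and adjusted over the list alone, with a median log2 fold change of -0.96 (camera adjusted p = 6.0e-27). The replication licensing gene MCM4 was at -1.91 ± 0.07, the cyclin gene CCNB1 at -1.71 ± 0.06 and the proliferation marker MKI67 at -1.63 ± 0.07 in the authors' deposited table. Cholesterol genes were negative as well, 19 of 24 with 0 positive in both counts (camera adjusted p = 2.8e-08). Examples from the authors' deposited table were the sterol reductase gene DHCR7 at -1.24 ± 0.06 and the acetyltransferase gene ACAT2 at -1.63 ± 0.09. Of 27 fatty acid genes 16 were negative and 8 positive over all genes, and 17 and 8 adjusted over the list alone (camera adjusted p = 0.00065). The desaturase genes FADS2 (-2.43 ± 0.07) and SCD (-1.04 ± 0.06) stood against the elongase gene ELOVL6 (2.73 ± 0.24) in the authors' deposited table. On ranks the fatty acid list had a camera adjusted p of 0.079.

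Genes that report RAS-MAPK output were positive in PANC1, 19 of 23 with 2 negative in both counts and a median of 1.13 (camera adjusted p = 2.9e-15). They included the epidermal growth factor receptor ligand genes EREG at 2.48 ± 0.07 and HBEGF at 2.52 ± 0.11, the AP-1 gene FOSL1 at 2.20 ± 0.08 and MYC at 1.46 ± 0.06 in the authors' deposited table. SPRY1 (-0.94 ± 0.08) and EPHA4 (-3.80 ± 0.39) were the 2 negative members in the authors' deposited table. YAP/TAZ targets were positive for 12 and negative for 2 of 17 over all genes, and 13 and 2 adjusted over the list alone (camera adjusted p = 6.1e-08). CCN1 was at 1.31 ± 0.06, CCN2 at 1.22 ± 0.06 and the ectonucleotidase gene NT5E at 2.65 ± 0.06 in the authors' deposited table. Ribosomal protein genes had 23 positive and 2 negative of 28 in both counts, with small values such as RPL3 at 0.84 ± 0.05 and RPS6 at 0.56 ± 0.05 in the authors' deposited table (camera adjusted p = 3.1e-05, and 0.39 on log2 fold changes).

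Epithelial genes of PANC1 were called negative as a list, with the most negative values in a few abundant members. Of 25 tested, 10 were negative and 4 positive in both counts, and the camera adjusted p was 2.7e-18 with the statistic and 0.28 on ranks. The list's median log2 fold change was 0.02 and its mean -0.92. KRT8 (-4.35 ± 0.06), KRT18 (-3.35 ± 0.05), KRT19 (-3.79 ± 0.05) and the E-cadherin gene CDH1 (-3.92 ± 0.10) were negative, and EPCAM (0.97 ± 0.10) and DSP (0.42 ± 0.08) positive, in the authors' deposited table. Mesenchymal genes went both ways, with 10 positive and 7 negative of 21 in both counts. ZEB2 was at 3.84 ± 0.51 and AXL at 0.81 ± 0.06 against S100A4 at -2.13 ± 0.06 and CDH2 at -2.03 ± 0.09 in the authors' deposited table. Immediate-early and heat-shock genes had 12 positive and 5 negative of 21 over all genes, and 13 and 5 adjusted over the list alone (camera adjusted p = 0.012, and 0.079 on ranks). The positive side held JUN (2.27 ± 0.06) and EGR1 (4.87 ± 0.25), and the negative side the heat-shock genes HSPA8 (-0.86 ± 0.06) and HSPH1 (-0.84 ± 0.06), in the authors' deposited table. Hypoxia-induced genes had 8 positive and 4 negative of 22 in both counts (camera adjusted p = 0.0091, and 0.28 on ranks), with STC2 at 1.47 ± 0.05 and EGLN3 at -3.29 ± 0.44 in the authors' deposited table. ATF4 and unfolded protein response genes had 12 and 9 of 28 over all genes and 13 and 9 adjusted over the list alone (camera adjusted p = 0.040, and 0.32 on ranks), with HSPA5 at 1.41 ± 0.06 and PSPH at -0.91 ± 0.08 in the authors' deposited table. With a preset correlation of 0.05, 7 of the 10 PANC1 list calls were left, and the hypoxia, ATF4 and immediate-early lists had camera adjusted p-values of 0.075, 0.21 and 0.081.

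Other PANC1 lists held large values of both signs and were not called. Among TGF-beta targets 13 of 19 were negative and 4 positive over all genes, and 13 and 5 adjusted over the list alone, with ID1 at -1.85 ± 0.10 and SMAD6 at -3.28 ± 0.20 against PMEPA1 at 0.86 ± 0.08 in the authors' deposited table. Interferon-stimulated genes had 16 negative and 7 positive of 28 in both counts, with IFIT1 at -2.64 ± 0.11 and RSAD2 at 4.79 ± 0.45 in the authors' deposited table (camera adjusted p = 0.068). Matrix genes had 11 positive and 7 negative of 25 in both counts, with the collagen IV gene COL4A1 at 2.56 ± 0.13 and COL5A2 at -1.47 ± 0.05 in the authors' deposited table. Class I presentation genes had 1 positive and 6 negative of 13 in both counts (camera adjusted p = 0.15). Set against random lists of like expression, the medians of the TGF-beta (-0.65), interferon (-0.46) and class I (-0.50) lists lay at percentiles 0.01, 0.06 and 1.77, and those of the matrix (0.43) and mesenchymal (0.43) lists at 99.84 and 99.62. Camera adjusted p-values of the TGF-beta, matrix and mesenchymal lists were 0.61, 0.11 and 0.70, and the mesenchymal test pointed to the negative side. The marker lists of other cell types hold human symbols here. Whether reads from host cells of another species were counted under these symbols was not tested. Over the 54 of these genes tested, the median mean normalised count was 5.54 in the authors' deposited table. Of these 54, 7 were at 64 or more, 4 of them fibroblast markers. CD68, a lysosomal gene that tumour cells can also express, was the most abundant, at 1.91 ± 0.07 with a mean normalised count of 1103 in the authors' deposited table. Fibroblast markers had 4 positive and 0 negative of 13 in both counts, with a median mean normalised count of 27.9 (camera adjusted p = 0.49). Among them the authors' deposited table listed COL3A1 at 1.05 ± 0.11 with a mean normalised count of 405 and COL1A1 at -0.13 ± 0.16 with 173.

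**Figure D3:**
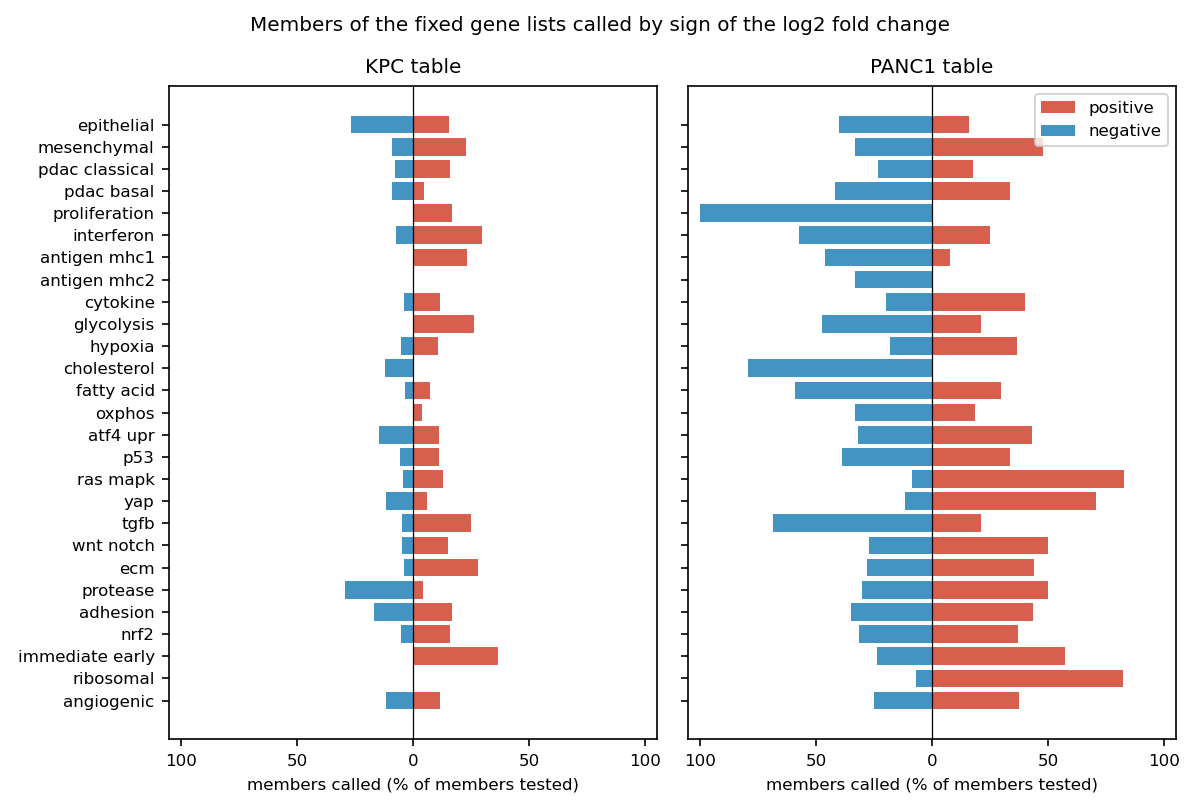
Members of the fixed gene lists called in each model. Each bar is the share of a list's tested members, in percent, with an adjusted p under 0.05 in the authors' deposited table, to the right for positive and to the left for negative log2 fold changes. In PANC1 all 30 cell cycle genes are on the negative side and 19 of 23 RAS-MAPK genes on the positive side.

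Comparing the models asks whether the selected lines of a mouse and a human model differed from their parental lines in the same genes. All samples of a selected group come from the same selected line. An effect of selection therefore cannot be told apart from other differences between a selected line and its parental line. Of 12,776 genes tested in both, 972 were called in both, 416 with the same sign and 556 with opposite signs, against 451 and 464 for independent lists. Both-positive overlap was 290 genes against 293 for independent lists (Fisher's exact test, two-sided, p = 0.856), and both-negative overlap was 126 against 158 (p = 0.0016). By the same exact test, opposite-sign overlaps were 411 against 318 for KPC positive with PANC1 negative (p = 1.4e-10) and 145 against 145.2 for the reverse (p = 1.0). Fisher's test takes genes as independent and calls as unrelated to level, so its p-values describe the overlap of lists only. Over all tested KPC genes, 1031 of 1157 positive and 206 of 922 negative calls were at a mean normalised count of 64 or more. For PANC1 these were 3698 of 4634 and 4128 of 4727. What shared level adds to the overlaps was not tested. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was -0.074 and Spearman's rho -0.074. Same and opposite exchange their meaning if the tables were written with the groups in different orders. Genes positive in both with the largest smaller value were the pentraxin gene NPTX1 (2.86 ± 0.34 in KPC and 4.97 ± 0.16 in PANC1) and NAV3 (2.30 ± 0.29 and 2.32 ± 0.17) in the authors' deposited tables. COL6A2 was also among the 8 (5.44 ± 0.37 and 1.93 ± 0.09 in the authors' deposited tables). CYP1A1, KCNQ1, IL18R1, EGR2 and ARAP3 completed the 8, with values from 1.82 ± 0.41 (KPC, ARAP3) to 3.51 ± 1.04 (PANC1, EGR2) in the authors' deposited tables. Genes negative in both were led by the adenosine receptor gene ADORA1 (-3.33 ± 0.56 and -3.29 ± 0.25) in the authors' deposited tables. SUSD4, MMP2, CACNA1G and LYPD6 came next, with a KPC mean normalised count from 5.86 (Mmp2) to 16.7 (Cacna1g) in the authors' deposited tables. Their KPC calls were lost after the level trend was subtracted, with adjusted p-values of 0.51, 0.54, 0.070 and 0.24 in the order named, and their KPC log2 fold changes went from between -3.01 (Mmp2) and -2.42 (Lypd6) to between -1.79 (Cacna1g) and -1.44 (Susd4). Without the filter on low values Susd4 and Mmp2 were at 0.051 and 0.053. After recentring LYPD6 of PANC1 and Cyp1a1 of KPC were both at 0.051. The fibroblast growth factor receptor gene FGFR2 (-2.39 ± 0.47 and -3.92 ± 0.41) and TIAM1 (-2.29 ± 0.58 and -2.59 ± 0.20) were also among the genes negative in both in the authors' deposited tables.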

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

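The explanation from a few abundant genes, the host-cell test on receptor genes, the check of group order and the shuffles with chromosome medians subtracted were chosen after the results were seen. The difference between models was tested per list under either order of the groups, since the order is unknown in both tables. With both tables read in the same order, 6 of 30 lists differed: cell cycle (camera adjusted p = 3.8e-20), RAS-MAPK (3.2e-08), epithelial (1.1e-06), YAP/TAZ (2.8e-06), protease (0.023) and fibroblast (0.0497). With one table turned, 7 of 30 differed: epithelial (2.1e-10), RAS-MAPK (4.0e-10), cell cycle (1.9e-09), cholesterol (1.1e-07), matrix (1.2e-07), immediate-early (1.5e-06) and ribosomal (0.029). The cell cycle, RAS-MAPK and epithelial lists were the 3 that differed in both readings, so for them the difference between the mouse and the human model does not depend on the order. For the epithelial list the median was -0.06 in KPC and 0.02 in PANC1, and its PANC1 camera adjusted p on ranks was 0.28. The difference between models was not tested on ranks, so for this list it is not shown beyond the members with large values.

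Low-level genes lay on the negative side of the KPC table. A few genes taking most of the counts would shift all levels alike, but the medians of genes at 64 or more and under 16 differed by 1.67. Silent genes shared the shift: 1184 olfactory and vomeronasal receptor genes had a median of -1.91, which argues against host cells for these genes, and 4 other silent families had a median of -1.55. Reads that do not come from transcripts, in unequal share between the groups, may account for it, but the receptor genes lay -0.46 from other genes of like level and their level had a rho of only 0.12 with exonic length, values that lie between the bounds set for and against. Host markers lay at percentile 4.05 of random lists of like level. Their median mean normalised count of 10.7 was inside the range of the receptor genes, which reached 37.0. The percentile therefore cannot tell host RNA from the shift that silent genes shared. A host contribution to the marker genes stays open, as does an untested effect of selection in vivo.

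Opposite signs between the models were more frequent than same signs. After the level trend of each table was subtracted Spearman's rho was -0.027, between no relation and the bound set for a trend-free one, so the level trend may account for part of it. A different order of the groups in one table cannot be told apart from a difference between the models: of the 2 lists called in both tables, 1 had the same sign (immediate-early) and the other the opposite sign (cell cycle). The KPC cell cycle call was lost after the level trend was subtracted (camera adjusted p = 0.58). In that setting the lists called in both were cholesterol, negative in both, immediate-early, positive in both, and YAP/TAZ, negative in KPC and positive in PANC1. A biological difference between a mouse and a human line also stays open, as untested.

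Neighbouring genes of KPC had like fold changes. Over 8749 genes the correlation 20 genes apart was 0.149, against at most 0.0347 in 1000 shuffles of gene order, and 0.148 at 5 genes apart, which argues against shared regulation or overlapping annotation of adjacent genes as the whole cause. Trends with GC content, exonic length and level were subtracted and 0.132 was left, which argues against them as the whole cause. A candidate explanation is gain or loss of chromosome material between the lines. With chromosome medians also subtracted, adjacent genes stayed alike at 0.090, against at most 0.0418 in 1000 shuffles, and the correlation was 0.001 at 5 and -0.009 at 20 genes apart. The likeness at 5 and 20 genes apart thus went with whole chromosomes, and that of adjacent genes did so only in part, with shared regulation or annotation open for the rest.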

How the results depend on the processing

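Leaving host markers out of the adjustment for genes called, recentring, level trend subtraction, the range at 64 or more, the t distribution, the correlation of 0.05, ranks, log2 fold changes, the turned table and, for shared genes, the fold threshold were chosen after seeing the data. No paired analysis was possible because the tables carry no value per library; for the same reason DESeq2 or limma-voom fits, other size factors, filters on scaled counts, a hepatocyte covariate, pseudocounts, an estimated correlation, the rotation test, other splits of the samples and leaving out replicates were not run. KPC calls went from 2079 to 1303 with an absolute log2 fold change over 1, 889 at an adjusted p of 0.01, 1345 at 64 or more, 1133 after trend subtraction and 0 with the t distribution (2132 at an unadjusted p under 0.05), which has fewer degrees of freedom than a fit that shares information between genes. Recentring gave 2149, with 23.5% positive against 55.7%. PANC1 calls went from 9361 to 2759 with the fold threshold and lay between 6342 and 9361 in the other settings. Called KPC lists went from 11 to 4 with a correlation of 0.05, 6 at 64 or more and 7 after trend subtraction, of which 4, 4 and 5 were among the 11; PANC1 lists went from 10 to 5 on ranks and 6 on log2 fold changes. Genes called with the same sign went from 416 to 114 with the fold threshold and 277 after trend subtraction. Pearson's r went from -0.074 to -0.012 at 64 or more, -0.028 after trend subtraction and 0.074 with one table turned, a reversal by construction. Apart from the constructions named, the cause was not tested. No called list or called named gene changed sign; Smad4 of KPC, not called, went from 0.20 to -0.02 after recentring and -0.04 after trend subtraction. With the t distribution 35 of the 65 named genes that were called lost their call, and 8 did after trend subtraction.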

Other observations

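The prediction for gain or loss of chromosome material was made before its result was seen; the gene families and single genes here were chosen after their values were seen. Replication histone genes were negative in PANC1, with 47 of 54 called negative and 0 positive and a median of -1.73, and had a median of -0.15 in KPC with 1 of 53 called. H1-5 was at -2.62 ± 0.08 and H2BC3 at -3.04 ± 0.12 in the authors' deposited table. Host genes of small nucleolar RNAs went both ways in PANC1, with 13 of 28 called positive and 9 negative and a median of 0.06 (quartiles -0.36 and 1.05), and GAS5 at 2.01 ± 0.05 and ZFAS1 at 1.88 ± 0.06 in the authors' deposited table. TXNIP, an arrestin-domain gene, was at 4.26 ± 0.08, the transporter gene ABCG2 at -4.51 ± 0.09 and the retinoic acid binding protein gene CRABP2 at -3.73 ± 0.06 in the authors' deposited table for PANC1.

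Beside Peg3, the authors' deposited table for KPC listed its neighbour Usp29 at -3.11 ± 0.51 and Zim1 of the same locus, not called, at -2.12 ± 0.85 (adjusted p = 0.0856). Of other imprinted genes looked at, Igf2r was at -3.31 ± 0.24 and Ndn, with no adjusted p, at -0.96 ± 1.65 in the authors' deposited table. No list of imprinted genes was tested. Of 5 genes tied to the inflammasome that were looked at, Aim2 at 4.21 ± 0.41 and Casp1 at 3.46 ± 0.60 were called in the authors' deposited table. Not called there were Gsdmd at -0.14 ± 0.23, Il18 at 1.32 ± 0.49 (adjusted p = 0.0587) and Il1b at -1.41 ± 1.09 (adjusted p = 0.39), and no list of such genes was tested. A further Y-linked gene, Ddx3y, was at -3.51 ± 0.78 with a mean normalised count of 11.9 in the authors' deposited table, beside Eif2s3y and Uty. Xist, the RNA of the inactive X chromosome, was negative as well, at -1.79 ± 0.62 with a mean normalised count of 23.6 (Wald test adjusted p = 0.0437) in the authors' deposited table. Low-level KPC genes were mostly negative, with a median of -1.38 at counts of 4 to 16 and -0.16 at 16 to 64. Values of Ddx3y and Xist with the level trend subtracted are not given here.

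Chromosome medians of KPC genes at a mean normalised count of 100 or more spread from -0.19 on chromosome 17 (414 genes) to 0.49 on chromosome 5 (590 genes), around 0.23 for all 8749. Chromosomes 9 (0.45) and 4 (0.39) were high, and 2 (-0.02) and 13 (-0.01) low. For 13 of 20 chromosomes the median lay outside the range of 1000 random gene sets of the same size. On chromosome 5, 187 genes were called positive and 2 negative. Copy number may differ between the KPC and the KPC LM2 samples for these chromosomes, but the tables hold no DNA measurement to test it. The correlation of 0.149 at 20 genes apart is no separate evidence. It was -0.009 after trends and chromosome medians were subtracted.

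The most abundant PANC1 rows were small non-coding RNAs that lack a poly(A) tail, with RN7SK at 412521 and RN7SL1 at 256746 mean normalised counts in the authors' deposited table, neither called. Rn45s and Malat1 led KPC at 231631 and 181227 in the authors' deposited table, and Malat1 was at 0.95 ± 0.19.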
